A study of Mus musculus with 6 samples.

How the data were processed

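Total RNA of DR4 mouse embryonic fibroblasts was labelled with biotin and hybridized to Affymetrix MOE430A and MOE430B arrays, 3 replicates on each, per the labels. Each array measures a transcript by a probe set, a group of short oligonucleotides. Cells were grown in D-MEM with 15% serum and LIF on 0.1% gelatin at 37 C and 5% CO2, and RNA was prepared with RNeasy columns, per the labels' protocols. The deposited values are MAS5 signal intensities on a linear scale, 1 column per array, with MAS5 named in the submitters' processing notes. Its version, background step and scaling settings are not given in the sources used here. The mean signal leaving out the top and bottom 2% of probe sets came to 1499.9 on the MOE430A arrays and 1499.8 on the MOE430B arrays, so each array had been scaled to 1 target, and each type separately. No level of 1 table was set against the other, and limma and camera ran within a table. What was combined over both was whether a gene lay above its own array's floor and the sign and size of deviations computed within each table. Deposited detection calls were not used here. Instrument records gave the scan day and fluidics station and no measurement.

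Probe sets numbered 22626 on MOE430A and 22511 on MOE430B after 64 control probe sets were left out of each. Gene names came from GEO's platform annotation, which can be old, with symbols updated through the gene identifier against RefSeq. A single symbol was given to 20380 MOE430A and 14661 MOE430B probe sets, of which 20351 and 14486 matched by identifier. Several symbols were given to 691 and 245, none of which is named, and 1555 and 7605 are unnamed here. Some list members had no probe set named here and are left out of the counts measured. No coordinates are given, because an array has no genome build.

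The planned floor was the 95th percentile of the bacterial poly-A control probe sets. Those controls had been added to the samples (Dap at 56379 to 82598 on MOE430A), so the floor was the array's median signal, the fallback fixed with it. A median floor puts 50% of the probe sets of every array below it, so the counts above it do not measure how many genes are expressed. A gene was above the floor if any of its probe sets was above the floor of its own array on all 3 arrays of a type. The 28 gene lists, the tests and the rule for named genes were set before the data were examined. Lists with at least 5 measured genes were tested by a two-sided Fisher's exact test against all other genes with 1 symbol, with Benjamini-Hochberg adjustment.

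Replicate 1 was compared with replicates 2 and 3 within each array type by limma (3.58.1, R 4.3.3), with lmFit and eBayes on log2(signal + 16), on probe sets whose mean log2 signal was above the mean log2 floor. Fold changes are on that scale, which understates the change of dim genes. With 1 array against 2 there is 1 residual degree of freedom, and the lone array is assumed to vary like the other 2. The moderated test then leans on the prior, whose degrees of freedom were 25.6 on MOE430A and 3.49 on MOE430B. Lists with at least 5 probe sets were tested with camera at a preset correlation of 0.01. The threshold was an adjusted p of 0.05 throughout.

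The tests were tried on simulated data, 20 draws per array type with changes added to 200 probe sets. The variances were drawn from the prior that limma fitted to these arrays, with independent normal noise. The moderated test's assumptions therefore held by construction, and the shares called and false below do not measure how far calls on the real arrays can be trusted. On MOE430A (11066 probe sets) 18.9% of changes of 1 on the log2 scale were called, 95.0% of changes of 2 and 100% of changes of 3, and 9.19% of all calls were false, which is above the nominal rate. On MOE430B (10594 probe sets) 0% was called at each size, so a count of 0 there says nothing about differences of up to 3 on the log2 scale. Of 1000 unchanged lists of 20 probe sets, camera gave 3.3% an unadjusted value under the threshold on either type. These lists were drawn at random with independent noise, so this share says nothing about lists whose probe sets vary together.

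Named genes are, per list, the 4 with the highest mean signal among those above the floor, or up to 3 where most members lay at or under it, and Hprt. This only chooses names and ranks no transcripts. A gene's value is its probe set with the highest mean signal on MOE430A, or on MOE430B where it has none there. For lists that did not pass, fewer are given. Pou5f1, Nanog, Sox2, Lif, Fgf2, the X- and Y-linked genes and the second probe sets are outside the rule and were chosen after their values were seen. Called genes that could be followed on MOE430B are also outside it, and all are given. For replicate 1, they are the 10 largest rises and 10 largest falls past the threshold per array type, or 5 per direction by p as values only, and list members called over all genes. For the spread, they are the 5 genes with the largest SD of log2 signal per type among probe sets above the floor on all 3 arrays.

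Alternatives were other floors, offsets of 1 and 64, quantile normalization, no filter, an eBayes trend, an estimated correlation, each replicate left out, each other replicate alone, the first probe set of a gene, and the probe sets present on both arrays. Figures were drawn with matplotlib 3.10.9.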

Results

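DR4 embryonic fibroblasts are mouse cells used as a feeder layer, the sheet of supporting cells on which embryonic stem cells are grown. The labels give them as fibroblasts from day 15 embryos, profiled as a control for the stem cell lines J1, R1 and V6.5, because some feeder cells stay among the stem cells at harvest. The stem cell lines were not analysed here. RNA from 3 replicates was measured on a pair of Affymetrix arrays, MOE430A with 22626 probe sets and MOE430B with 22511, which makes 6 samples. Replicate 1 came from 12x10e6 cells at 2.4 ug/ul RNA, and replicates 2 and 3 each came from 3x10e6 cells at 3.0 ug/ul, in the labels' notation. Nothing in the labels says that the replicates were separate cultures, so limma's p-values measure only the spread between these samples, which may be technical. Fisher's exact and binomial tests count genes, and their p-values hold no spread between samples. The number of arrays limits the precision of every value. Signals below are MAS5 intensities, given as mean ± SD (n = 3 arrays) and taken on MOE430A unless MOE430B is named. Probe sets differ in how brightly they hybridize, so signals of different probe sets do not rank transcripts, and serve here only to set a floor and to choose which genes are named.

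The first question was which genes feeder cells express. DR4 cells had the transcripts of connective tissue cells: all 19 measured members of the fibroblast and mesenchyme list lay above the array's median signal on all 3 arrays. The intermediate filament gene Vim had a signal of 149376 ± 17104, the type I collagen genes Col1a2 and Col1a1 had 145435 ± 24758 and 106848 ± 26287, and the matrix protein gene Sparc had 109530 ± 10908. Of the 19 measured pluripotency genes, 2 were above the median (10.5%, and 21.1% without replicate 3), and the core stem cell factors Pou5f1 (109 ± 136), Nanog (91.6 ± 47.5) and Sox2 (29.3 ± 3.37) were not. The array's median served as the floor, and lay at 689, 685 and 734 on the MOE430A arrays and at 849, 917 and 907 on the MOE430B arrays. The highest tryptophan control, a bacterial probe set without a mouse target, lay at 614, 757 and 786 on MOE430A and at 1989, 2348 and 2229 on MOE430B. Whether this control had been added to the samples is not known. It was above the floor on all 3 MOE430B arrays, so a gene counted only through MOE430B may not be expressed. Above the floor, the array's median, on all 3 arrays were 9600 MOE430A probe sets (42.4%) and 8384 MOE430B probe sets (37.2%). By genes with 1 symbol, these made 9944 of 18193 (54.7%). Of 26 lists tested, 6 had more genes above the floor than other genes did and 6 had fewer.

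The contractile and matrix programmes stood with the fibroblast list, which had an adjusted p of 0.000451 in a two-sided Fisher's exact test with Benjamini-Hochberg adjustment over the 26 lists. In the myofibroblast and smooth muscle list, 14 of 15 genes were above the floor (adjusted p = 0.00797). Among its members were smooth muscle actin Acta2 (96534 ± 33856), the collagen cross-linking enzyme Lox (64126 ± 12930), the actin-binding Tagln (33626 ± 16716) and the tropomyosin Tpm2 (25777 ± 6747). Among matrix remodelling enzymes and their inhibitors, 14 of 16 were above the floor (adjusted p = 0.0233). The protease inhibitors Timp2, Timp3 and Timp1 had signals of 55697 ± 17162, 36204 ± 5129 and 31273 ± 9610, and Loxl1 had 25116 ± 635.

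Housekeeping and stress lists also passed in this direction. All 14 cholesterol synthesis genes were above the floor (adjusted p = 0.00197), among them Hmgcs1 (7044 ± 2816), Fdps (6728 ± 1738), Insig1 on MOE430B (3810 ± 1001) and Nsdhl (3686 ± 1201). All 10 antioxidant response genes were above it (adjusted p = 0.00797), with Sqstm1 at 17934 ± 1066, the thioredoxin reductase Txnrd1 at 6684 ± 2520, Gsta4 at 4786 ± 1472 and Gstm1 at 4686 ± 648. In the unfolded protein and amino acid stress list, 13 of 14 genes were above it (adjusted p = 0.013), with the chaperone Hspa5 at 18209 ± 5062, Phgdh at 10799 ± 3413, Atf4 at 10124 ± 1566 and Hsp90b1 at 9839 ± 2148. With a fixed signal of 200 as the floor none of these 6 lists passed. Fisher's test gave an adjusted p of 0.0899 for the fibroblast list and 0.171 for the myofibroblast list. It gave 0.209 for the cholesterol and unfolded protein lists and 0.331 for the matrix and antioxidant lists. The fibroblast and myofibroblast lists both stood at 100% there. With 15387 of 22626 MOE430A probe sets above this floor, little room was left for a difference.

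Markers of other cell types were mostly at or under the floor. In the pluripotency list (adjusted p = 0.00118), Fgf4 (1179 ± 92.1) was above it by 1 of its 4 probe sets and Esrrb by 1 of its 3. None of 9 erythroid genes was above it (adjusted p = 0.0042), and 11.1% were without replicate 1 (adjusted p = 0.0176). In the skeletal muscle list 3 of 20 genes were above it (adjusted p = 0.00264), namely Actc1 (1176 ± 276), Des (1109 ± 178) and Ckm (1064 ± 150.0). In the epithelium list 2 of 14 were (adjusted p = 0.00797), Krt8 at 1502 ± 391 and Epcam, which counted through an MOE430B probe set while its MOE430A signal was 62.1 ± 22.5. In the liver and endoderm list 2 of 14 were (adjusted p = 0.00797), Gata6 at 1019.9 ± 172 and Apob through an MOE430B probe set. In the endothelium list 3 of 14 were (adjusted p = 0.0322), Kdr at 1407 ± 199.9, Egfl7 at 791 ± 124 and Flt1. Flt1 counted through another probe set than the one with its signal of 1163 ± 873, which was under the floor on at least 1 array. Without replicate 1 the endothelium list no longer passed (adjusted p = 0.0612), and with the 75th percentile as the floor, added after the data were seen, the erythroid and epithelium lists did not (adjusted p = 0.102 and 0.107). With a fixed signal of 200 as the floor the epithelium, liver and endothelium lists did not (adjusted p = 0.33, 0.0814 and 0.171).

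The other 14 tested lists did not pass, and are given as counts. Of the 16 macrophage genes 5 were above the floor (adjusted p = 0.0963), with Lyz2 at 2030 ± 580 and Csf1r at 1860 ± 144. The same count of 5 of 16 held for neurons and glia (adjusted p = 0.0963), with Stmn2 at 3149 ± 450 and Ncam1 at 2601 ± 606. Cartilage and bone had 3 of 11 (adjusted p = 0.0963), with Col2a1 at 4400 ± 810, and the adipocyte list had 3 of 9 (adjusted p = 0.342), with Lpl at 3341 ± 1962. The Hox list had 12 of 29 (adjusted p = 0.221), with Hoxc6 at 3402 ± 399, Hoxa9 at 2202 ± 668, Hoxa11 at 1578 ± 194 and, on MOE430B, Hoxc10 at 4597 ± 1834.

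Cell cycle genes were above the floor in 15 of 19 cases (adjusted p = 0.0657), including the ribonucleotide reductase subunit Rrm2 (4639 ± 1720), Pcna (4207 ± 497), Cdk1 (3826 ± 524) and Cdc20 (2572 ± 131). This list passed without replicate 1 (adjusted p = 0.0433) and without replicate 2 (adjusted p = 0.0398). The p53 target and cell cycle arrest list had 13 of 16 (adjusted p = 0.0688), with the cell cycle inhibitor Cdkn1a at 34890 ± 3206, Ccng1 at 21346 ± 3980, Phlda3 at 17828 ± 789 and Mdm2 at 6648 ± 1289. Whether the cells had been treated to stop dividing, as feeder layers often are, is not stated in the labels.

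Secreted growth factors and their binding proteins were above the floor in 17 of 22 cases (adjusted p = 0.0784). Igf2, a growth factor of the embryo, had a signal of 86013 ± 27276, Igfbp4 had 22102 ± 10624, the BMP antagonist Grem1 had 10645 ± 2524 and Igfbp5 had 10525 ± 5944. Lif, the factor that holds mouse stem cells undifferentiated and was also added to the medium, had 358 ± 193, and Fgf2 had 270 ± 65, both under the floor. Chemokines and inflammation had 11 of 15 (adjusted p = 0.221), with Cxcl12 at 20402 ± 6213 and Csf1 at 8975 ± 868. The interferon response had 8 of 12 (adjusted p = 0.565), with Ifit1 at 3897 ± 1476, and immediate early genes had 10 of 15 (adjusted p = 0.459), with Egr1 at 4255 ± 852. Hypoxia and glycolysis had 12 of 14 (adjusted p = 0.0523), with Pgk1 at 56406 ± 14650, and heat shock had 9 of 10 (adjusted p = 0.0523), with Hspa8 at 40371 ± 1293. Imprinted genes, expressed from the copy of 1 parent, had 12 of 15 (adjusted p = 0.0963), with Gnas at 52965 ± 5446 and Dlk1 at 24699 ± 7524.

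Xist, the RNA of the inactive X chromosome, was above the floor (1742 ± 422), and the Y-linked genes Eif2s3y (431 ± 208), Kdm5d (391 ± 117) and Uty (356 ± 38.3) were not; this list was too small to test. Hprt, the purine salvage gene that DR4 mice are known to lack in working form, had a signal of 2233 ± 251, above the floor. Where its probes lie relative to the altered part of the gene was not determined, so this value checks nothing about the cells' genotype. With a fixed signal of 200 as the floor 3 lists passed, all with fewer genes above it (pluripotency, skeletal muscle and erythroid), and with the highest poly-A control 1 did, the fibroblast list. With the highest tryptophan control as the floor 16 passed, among them all 12, and with the first probe set of each gene 18 passed, among them all 12. The p53 target, secreted growth factor, heat shock and imprinted lists passed under both of these, and the hypoxia and neuron lists with the first probe set. With the 75th percentile as the floor the p53 target and imprinted lists passed (adjusted p = 0.0297 and 0.0175).

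**Figure D1:**
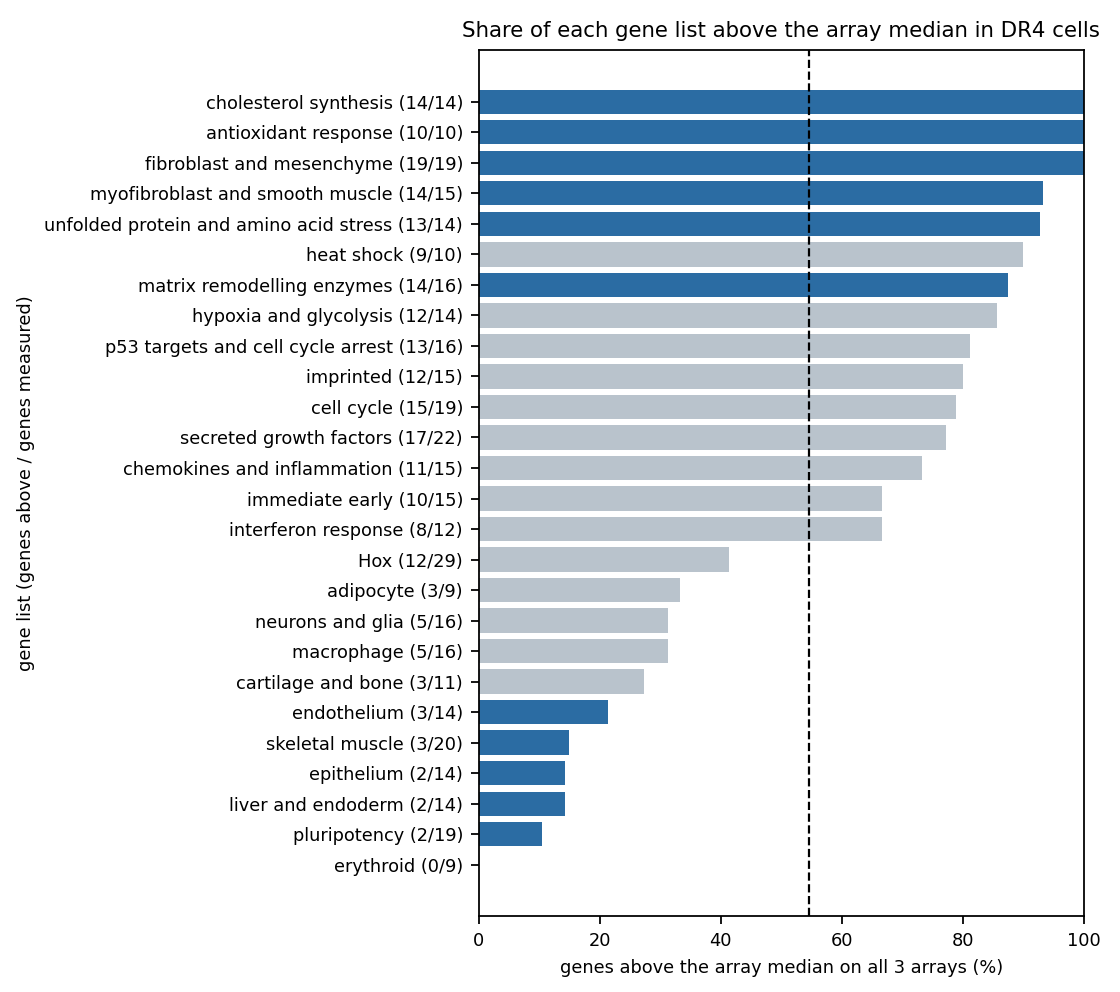
Percentage of each gene list's measured genes that lay above the array's median signal on all 3 arrays of a type (horizontal axis, %), with the number above and measured beside each list; blue bars passed Fisher's exact test at an adjusted p of 0.05, grey bars did not, and the dashed line is the share over all 18193 genes (54.7%). Fibroblast, antioxidant and cholesterol genes reach 100%, while pluripotency genes reach 10.5% and erythroid genes 0%.

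The spread between the replicates was asked next, because it is the error of a control profile. Genes above the floor varied with a median SD of 0.24 on the log2 scale on MOE430A (median coefficient of variation 16.5%) and 0.28 on MOE430B (19.4%). Among probe sets above the floor on all 3 arrays, the genes that varied most on MOE430A were the redox enzyme gene Cyb5r3 (1047, 1207 and 10939 in replicates 1, 2 and 3), the nuclear RNA Malat1 (1577, 7326 and 19168), Igf2 on 1 of its probe sets (817, 735 and 5482), the imprinted RNA Meg3 (872, 1513 and 6218) and Igfbp4 (1360, 2156 and 8113). By the same limit they were, on MOE430B, Sned1 (4350, 19488 and 64158), Rtel1 (17615, 2333 and 26134), Agps (8181, 1021 and 1220), Nup62 (3774, 28625 and 23593) and Ecrg4 (2140, 11791 and 16247).

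Pearson's r across probe sets above the floor was 0.949 between replicates 1 and 2, 0.928 between 1 and 3 and 0.948 between 2 and 3 on MOE430A. The same values on MOE430B were 0.875, 0.869 and 0.885. Genes are not independent replicates, so these describe the arrays. More than 2-fold apart were 255, 432 and 240 of 9600 MOE430A probe sets for these pairs, and 490, 553 and 383 of 8384 on MOE430B. The replicates therefore held different values, and each was counted as 1 sample. Signal ratios of the 3' to the 5' end of beta-actin were 1.05, 1.17 and 1.09 on MOE430A and 1.02, 1.33 and 1.10 on MOE430B, lowest in replicate 1. Those of Gapdh were 1.27, 1.16 and 0.85 on MOE430A and 1.32, 1.24 and 0.80 on MOE430B, highest in replicate 1.

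Replicate 1 was then set against replicates 2 and 3, the 1 difference among arrays of a type that the labels record. On MOE430A the prostaglandin synthase gene Ptgs2 was at least 5.02-fold higher in replicate 1, the DNA repair nuclease gene Fen1 at least 3.75-fold, and Cck, which encodes a peptide hormone, 4.72-fold. The imprinted gene Peg3 was at least 2.37-fold lower, the fibrillin gene Fbn2 at least 3.69-fold and Malat1 7.45-fold. In all, limma called 78 of 11066 probe sets at an adjusted p of 0.05, 24 higher and 54 lower in replicate 1, among 900 with an unadjusted p below 0.05. They named 66 genes. With 1 array against 2 no value measures the spread of replicate 1 itself, so the count describes these arrays. On MOE430B limma called 0 of 10594, with 767 at an unadjusted p below 0.05, a lowest adjusted p of 0.405, and 0 calls also with an eBayes trend.

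A lower bound was given where an array of the dim side lay under its floor, with the floor in its place. By that rule the other rises named were the cardiac ankyrin repeat gene Ankrd1 (at least 2.83-fold on 1 probe set, and at least 3.85-fold on the other, where 1 of the 2 dim arrays was above its floor), the platelet chemokine gene Ppbp (at least 3.12-fold), Prss12 (at least 2.77-fold), Zyx (at least 2.59-fold), Nme1 (4.10-fold) and Txnrd1 (at least 3.10-fold). For Txnrd1 too, 1 of the 2 dim arrays was above its floor. Txnrd1 had an adjusted p of 0.0445 in limma, and its log2 difference was 1.07 without replicate 2, while without replicate 3 the dim array was under its floor. The other falls were Zdhhc12 (at least 4.77-fold), the complement gene C1s1 (at least 3.19-fold), Sdc3 (at least 2.62-fold), the interleukin 1 receptor gene Il1r1 (at least 2.22-fold), Serpinb1a (at least 1.91-fold), Tns2 (at least 1.90-fold) and Mme (at least 1.90-fold). For Serpinb1a 1 of the 2 brighter arrays, that of replicate 2, was itself under its floor, and the bound rested on which array replicate 1 was set against, at least 3.90-fold without replicate 2 and with no fold to give without replicate 3. Malat1, above the floor on all 3 arrays, had a log2 difference of -3.59 without replicate 2 and -2.20 without replicate 3. The bound for Peg3 was 3.20-fold without replicate 2 and 1.75-fold without replicate 3, and that for Sdc3 was 3.59-fold and 1.91-fold. That for Prss12 moved little, at 2.68-fold and 2.87-fold.

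Probe sets of 1 gene did not always move alike. Of the 19 genes named here, 8 had another MOE430A probe set in the test, and for 2 of them, Ptgs2 and Ankrd1, another was also called. The rest, with Fen1, Cck and Fbn2 among them, had no other in the test, so each of their calls rested on 1 probe set. Zyx had a signal of 14104 in replicate 1 against 11396 and 9300.1 on its second probe set, and Nme1 had 6112 against 4875 and 4217. One of the other Sdc3 probe sets and one of the other Malat1 probe sets had the opposite sign.

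On MOE430B no probe set passed, and the smallest p-values belonged to values only. Cbx7 had a signal of 106 in replicate 1 against 1915 and 3920.3, Spats1 205 against 3066 and 2405, Aknad1 340.2 against 3486 and 3409.8, Mia3 406 against 3317 and 3491, and Cdv3 224 against 2247 and 1833. In the other direction Agps had 8181 against 1021 and 1220, Men1 4957 against 602 and 743, Cdk3 4219.8 against 592 and 594, 2610316D01Rik 4065 against 505 and 489, and 4933412E24Rik 3351 against 587 and 713.

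The MOE430A arrays of replicates 1 and 2 shared a scan day and a fluidics station, and that of replicate 3 had another of each. On MOE430B the arrays shared a day, and replicate 1 alone was on another station than replicates 2 and 3, so station and replicate 1 cannot be told apart there. Within the shared day on MOE430A, the called falls had a median log2 difference of -1.71 and the called rises of 1.90, with replicate 1 minus replicate 2. These probe sets had been called for a large difference of replicate 1, so the medians say nothing about the day, and a fit with the day as a block leaves no degree of freedom. The count fell to 0 after quantile normalization and to 0 without the filter, and replicate 3 alone against the other 2 gave 21 and replicate 2 alone 0. For 2 of the genes above the floor on all 3 arrays the size stayed after quantile normalization. Cck had a log2 difference of 2.24 (SE 0.37) before and 2.25 (SE 0.31) after it, and Malat1 had -2.90 (SE 0.43) and -2.88 (SE 0.57). Leaving out the filter cannot change the size, only the SE, which was then 0.38 for Cck and 0.75 for Malat1. The prior degrees of freedom went from 25.6 to 6.02 and 2.41, and limma's adjusted p went to 0.281 and 0.73 for Cck and to 0.403 and 0.781 for Malat1.

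At the preset correlation of 0.01, limma's camera called 11 of 19 lists on MOE430A, 7 higher and 4 lower in replicate 1, and none of them held with an estimated correlation, where the lowest adjusted p was 0.531. With an estimated correlation camera has only the 1 residual degree of freedom, so a list could hardly pass. That loss therefore does not show whether correlation undid the calls. The estimated correlations rest on the same 1 degree of freedom. They were above the preset for interferon (0.60), matrix remodelling (0.42), myofibroblast (0.30), secreted growth factor (0.11) and antioxidant genes (0.06). For the other called lists they were below it, among them the imprinted list (-0.026). Imprinted genes were called lower, with a median log2 difference of -0.77 over 27 probe sets of 12 genes, 20 of these probe sets lower and 7 higher. Secreted growth factors (median -0.53), fibroblast and mesenchyme genes (-0.36) and matrix remodelling enzymes (-0.35) were called lower as well. Myofibroblast and smooth muscle genes were called higher, with a median of 0.70 over 19 probe sets of 13 genes, 16 of these probe sets higher. Probe sets of 1 gene are not independent, yet the preset correlation takes them nearly so, which can make camera's p too small. Replicate 1 had the highest Gapdh and the lowest beta-actin ratio of the 3' to the 5' end on both array types.

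In the imprinted list (adjusted p = 1.6e-08 by camera; adjusted p = 0.531 with an estimated correlation), 4 probe sets were called lower over all genes tested, and 10 lower and 1 higher adjusted over the list alone. The 4 were Peg3, the growth inhibitor Cdkn1c (1077 in replicate 1 against 3138 and 4401), Mest (1444 against 4257 and 5564) and Plagl1 (6777 against 19978 and 21186). In the secreted growth factor list (adjusted p = 3.4e-05; adjusted p = 0.531 with an estimated correlation), 1 was called lower over all genes and 7 adjusted over the list alone. The 1 was Igfbp5, at 4454 against 16334 and 10786.5. The matrix remodelling list (adjusted p = 0.000215; adjusted p = 0.704 with an estimated correlation) had 1 and 3 in the same way, with the collagenase Mmp13 at 896 against 2804 and 3090.02. The fibroblast list (adjusted p = 0.000253; adjusted p = 0.531 with an estimated correlation) had 0 and 0, with 28 of 34 probe sets lower.

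In the myofibroblast and smooth muscle list (adjusted p = 1.6e-08; adjusted p = 0.531 with an estimated correlation), 2 were called higher over all genes and 6 adjusted over the list alone. The 2 were the matricellular gene Ccn2 (20188.5 against 7260 and 6188) and the calponin gene Cnn1 (7562 against 2997 and 1381). Antioxidant genes (median 0.62, adjusted p = 1.3e-05; adjusted p = 0.531 with an estimated correlation) had 1 over all genes and 2 adjusted over the list alone. Chemokines and inflammation (median 0.16, adjusted p = 0.018; adjusted p = 0.531 with an estimated correlation) had 2 and 2, both of them probe sets of Ptgs2. Immediate early genes (median 0.19, adjusted p = 0.00158; adjusted p = 0.531 with an estimated correlation) had 1 and 1, the nuclear receptor gene Nr4a1 at 5782 against 1409 and 1671. Interferon genes (median 0.55, adjusted p = 0.000173; adjusted p = 0.654 with an estimated correlation) had 0 and 3, heat shock genes (median 0.47, adjusted p = 1.3e-05; adjusted p = 0.531 with an estimated correlation) 0 and 2, and hypoxia and glycolysis genes (median 0.35, adjusted p = 0.00158; adjusted p = 0.531 with an estimated correlation) 0 and 0.

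Without replicate 2 and without replicate 3, the medians were 0.01 and 0.25 for chemokines, whose call was also lost with quantile normalization (adjusted p = 0.0732). They were 0.94 and 0.44 for myofibroblast genes, -0.56 and -0.16 for matrix remodelling, 0.61 and 0.30 for interferon, 0.72 and 0.40 for antioxidant and 0.34 and 0.26 for immediate early genes.

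The other 8 lists on MOE430A did not pass: macrophage (median 0.10), endothelium (-0.20), neurons and glia (0.05), cell cycle (0.06), p53 targets (-0.04), unfolded protein stress (-0.07), cholesterol synthesis (-0.15) and Hox (-0.08). The sign of 4 of these medians turned with the replicate left out: without replicate 2 and without replicate 3 they were 0.22 and -0.49 for cholesterol synthesis, 0.14 and -0.19 for unfolded protein stress, 0.23 and -0.04 for neurons and glia and 0.05 and -0.09 for macrophage genes. The other 4 kept their sign, with -0.12 and -0.04 for endothelium, 0.10 and 0.25 for cell cycle, -0.30 and -0.004 for p53 targets and -0.03 and -0.24 for Hox. In the endothelium and unfolded protein lists the mean had the opposite sign to the median. Of 5 lists tested on MOE430B 0 passed, with median log2 differences of -0.52 for imprinted genes (adjusted p = 0.104), -0.61 for secreted growth factors (adjusted p = 0.193), 0.64 for hypoxia and glycolysis (adjusted p = 0.193), 0.32 for Hox genes (adjusted p = 0.472) and 0.05 for chemokines (adjusted p = 0.472). Without replicate 2 and without replicate 3, these MOE430B medians were -0.02 and 0.21 for Hox and -0.16 and 0.26 for chemokines, so both turned. The hypoxia median was 0.42 without replicate 2 and 0.38 with quantile normalization. Replicate 3 alone against the other 2 gave 9 MOE430A lists at the preset correlation and replicate 2 alone gave 2, in contrasts that use the same arrays.

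**Figure D2:**
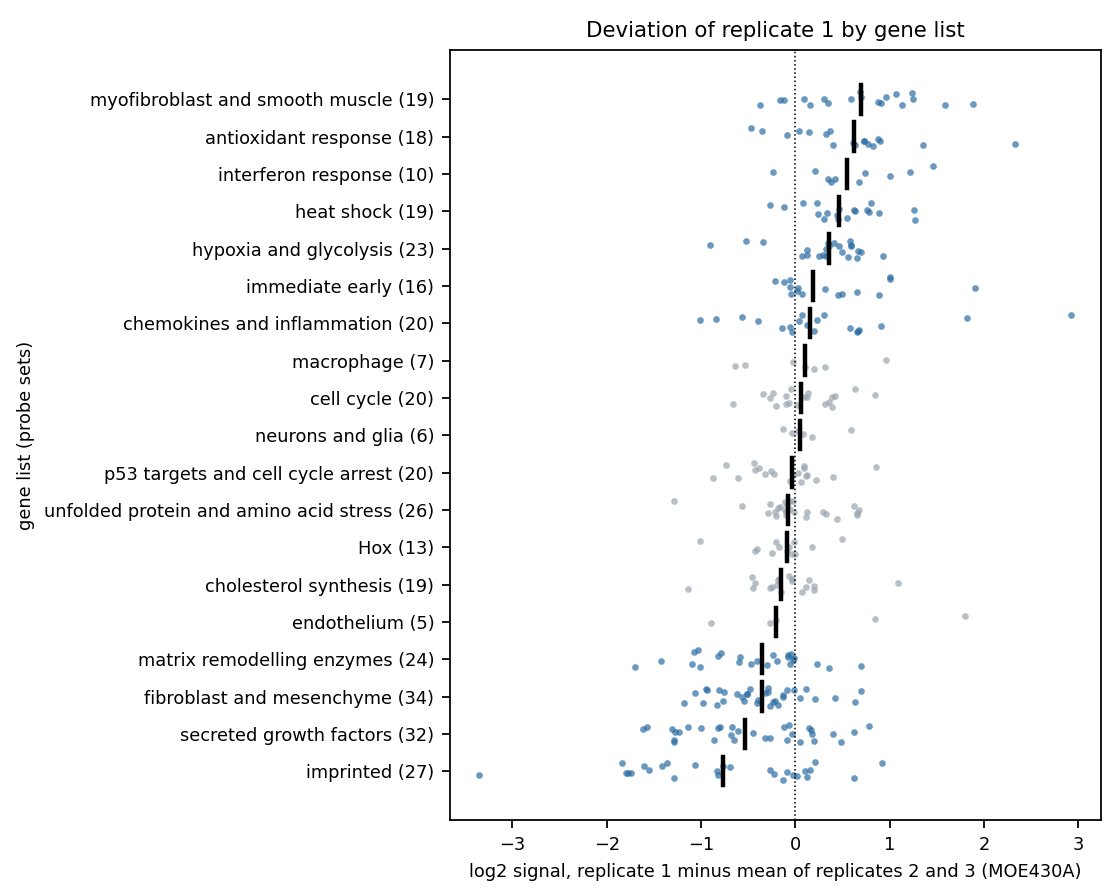
Log2 signal of replicate 1 minus the mean of replicates 2 and 3 on MOE430A (horizontal axis) for each probe set (point) of the 19 lists tested, with the list's median as a black bar and the number of probe sets in brackets; blue lists passed camera at the preset correlation of 0.01, grey ones did not. The imprinted list has the lowest median (-0.77) and the myofibroblast and smooth muscle list the highest (0.70). With an estimated correlation, at 1 residual degree of freedom, a list could hardly pass and none did.

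**Figure D3:**
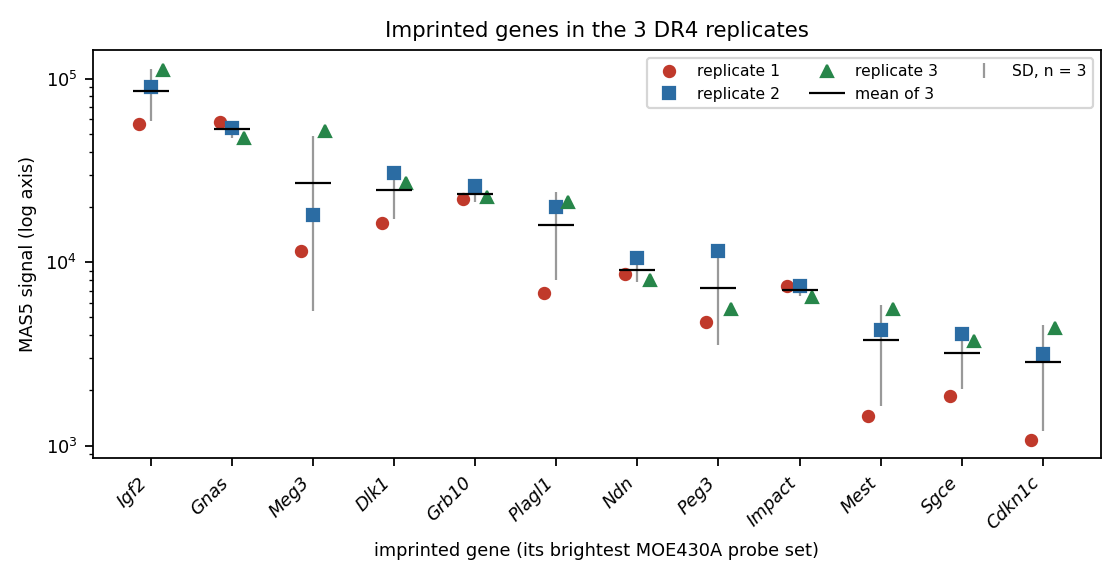
MAS5 signal on MOE430A (vertical log axis) of each imprinted gene whose brightest probe set lay above the floor, with 1 coloured point per replicate, the mean as a black bar and the SD (n = 3) as a grey line. Replicate 1 lies lowest for Cdkn1c (1077), Mest (1444) and Plagl1 (6777), while Gnas, Ndn and Impact do not follow.

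The labels give the same replicate numbers, cell numbers and RNA concentrations on both array types, but do not say that 1 RNA preparation went on both. Taking it that 1 did, the deviation of replicate 1 was compared between them. Of the genes called on MOE430A, 11 had other probe sets in the MOE430B test, and 8 had the same sign there, namely Ecrg4 (log2 difference -2.12 on MOE430A and -1.85 on MOE430B), Plagl1 (-1.60 and -0.54), Malat1 (-2.90 and -0.39), Fbn2, Wdfy3, Tenm3, Neo1 and Hivep3. Those with the opposite sign were Fhl1 (1.85 and -0.13), Ptprs and Sema3f. The genes without values were all lower in replicate 1 on MOE430A and lay under its floor there, so only their sign was used. Over the 11, the median on MOE430B, in the direction seen on MOE430A, was 0.39. An even chance was not excluded by a two-sided exact binomial test (p = 0.227). Over all 1414 genes with probe sets in both tests, 56.2% had the same sign (95% Clopper-Pearson interval 53.5 to 58.8%), with a Pearson's r across genes of 0.169. The same share was 54.2% (r = 0.0813) for the deviation of replicate 2 and 55.6% (r = 0.156) for that of replicate 3. The 3 deviations are computed from the same arrays and are not independent. Of the genes more than 2-fold off on MOE430A, 39 of 49 had the same sign on MOE430B for replicate 1 (two-sided exact binomial p = 3.85e-05, with genes taken as independent), 10 of 16 for replicate 2 (p = 0.454) and 30 of 45 for replicate 3 (p = 0.0357). The 100 probe sets present on both arrays had the same sign in 66 cases for replicate 1 (r = 0.549), 61 for replicate 2 (r = 0.430) and 70 for replicate 3 (r = 0.378).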

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

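The scan day test of the probe sets called in replicate 1 was set before its result was seen; the other tests in this part were chosen after the values were seen, and the bounds for degraded RNA were reset then to count Gapdh too. No biological explanation was tested, since all samples are of 1 cell type.

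A control probe set for the B1 repeat, a short interspersed element found throughout the mouse genome, is not part of the comparisons and differed between the replicates. Its highest replicate was 3.17 times its lowest on MOE430A (23839, 42919 and 13543 in replicates 1, 2 and 3). On MOE430B the highest was 2.55 times the lowest (84844, 149357 and 58573). Replicate 2 was highest and replicate 3 lowest on both. A control probe set for the B2 repeat differed 1.04 times on each. Another control probe set with b2 in its name was also highest in replicate 2 on both. It had 2272, 3044 and 2284 on MOE430A and 8216, 11678 and 8222 on MOE430B. For the B1 repeat, array noise is argued against by the second array of each RNA. That array gave the same highest and lowest replicate and the range of 2.55. This holds only if arrays of 1 replicate number hold 1 RNA, which the labels do not say. More unspliced or genomic template in replicate 2 may play a part: probe sets unnamed here lay higher than named ones in that replicate on MOE430B, by 0.12 on the log2 scale (0.1229, bootstrap SE 0.0128), but not on MOE430A (-0.0186, SE 0.0232), so this stays open. The bound for that test was reset to 2 bootstrap SE after the values were known; as first written, asking that replicate 2 lie highest on both array types, it would have counted against this explanation.

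The 78 probe sets called in replicate 1 on MOE430A are a further pattern. A difference of scan day was not decided: all 78 differed by more than 2-fold between replicates 1 and 2, scanned on 1 day, but that was nearly fixed by calling them for a large difference of replicate 1. Degraded RNA in replicate 1 was not decided by the order of the ratios. Its beta-actin 3' to 5' ratio, 1.05 on MOE430A and 1.02 on MOE430B, was the lowest of the 3. Its Gapdh ratio, 1.27 and 1.32, was the highest. No ratio of any replicate was above 1.33, whereas ratios above 3 had been asked of degraded RNA. As first written, with beta-actin alone, the test would have counted against this explanation. Noise of single arrays may account for part of the calls: 8 of the 11 called genes that could be followed had the same sign on MOE430B (two-sided exact binomial p = 0.227), whereas of all genes more than 2-fold off on MOE430A, a wider set, 39 of 49 did (p = 3.85e-05), beside 30 of 45 for the deviation of replicate 3 (p = 0.0357). The number of cells, the RNA concentration and, on MOE430B, the fluidics station differed with replicate 1 and cannot be told apart from it with 1 array.

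The imprinted genes' lower signals in replicate 1 are the last pattern. Scan day was not decided: the list's median on MOE430A between replicates 1 and 2, which shared a day, was -0.65 (-0.6531), but that difference is part of the contrast for which the list was singled out. Noise of single arrays stays open: on MOE430B the list's median had the same sign with an unadjusted camera p of 0.0208 at the preset correlation, but 0.386 with an estimated correlation, over 9 probe sets of 3 genes. That both correlations should pass was required after these values were known. As first written, asking only for the preset correlation, the test would have counted against noise. With an estimated correlation there is 1 residual degree of freedom, so that value could hardly pass and decides nothing. The preset correlation takes 9 probe sets of 3 genes as nearly independent, so it does not decide either.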

How the results depend on the processing

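Other floors, the lists with another replicate alone and the list medians without a replicate were partly added after seeing the data: the tryptophan control and 75th percentile floors, the list tests of replicates 2 and 3 alone, and those medians. A median floor, also named as another setting before the data were examined, is the floor used, so it gave no second value. No paired analysis was possible because the comparison is between replicate numbers, and the array types that share them were scaled separately. What limits these results is 1 array against 2 and a floor that is a rank, with no signal over background to set it.

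Probe sets above the floor on MOE430A numbered 9600, and 36 with the highest poly-A control, 15387 with a signal of 200 and 4689 with the 75th percentile as floor. On MOE430B they numbered 8384, and 2, 15764 and 3980, and 3649 with the highest tryptophan control. The poly-A controls had been added to the samples, so few probe sets lie above them, and the other counts follow from a higher or lower floor. Lists passing fell from 12 to 1 with the poly-A floor and to 3 with a signal of 200, and rose to 16 with the tryptophan floor and 18 with the first probe set of a gene, the 12 included in both; with the 75th percentile 12 passed, 10 of them shared. With the poly-A floor 0% of the members of the myofibroblast, matrix remodelling, unfolded protein, cholesterol and antioxidant lists were above it, which reversed their direction, since few probe sets are left. With replicates left out, the median SD of log2 signal was 0.18 to 0.21 on MOE430A (0.183 to 0.210) and 0.21 to 0.24 on MOE430B (0.215 to 0.239), as an SD over fewer arrays; without the filter it was 0.36 and 0.49. The 78 calls in replicate 1 became 0 with quantile normalization, 0 without a filter and 164 with an eBayes trend (72 shared), and replicate 2 alone gave 0 and replicate 3 alone 21. The prior degrees of freedom were 6.02 with quantile normalization, 2.41 without a filter and 148 with the trend, against 25.6. Offsets of 1 and 64 gave 74 and 86, and Txnrd1 missed the threshold with an offset of 1. The 11 MOE430A lists became 0 with an estimated correlation and 2 with replicate 2 alone, and stayed at 10 with quantile normalization and 11 with an offset of 64. With an estimated correlation the test has 1 residual degree of freedom, so that count of 0 was nearly fixed. The unfolded protein list, which did not pass, had a median of -0.08 (-0.077) with quantile normalization, where the test's direction reversed. Genes of the same sign on both types rose from 56.2% to 66% with the probe sets present on both. Apart from the poly-A, filter, trend, estimated correlation and construction cases named here, the cause was not tested.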

Other observations

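Some values belong to no comparison, and no test was run on them. Gapdh 3' signal was higher in replicate 1 than in the other replicates on both array types, at 94411 against 60801 and 56345 on MOE430A and 384695 against 204546 and 177366 on MOE430B. Meg3, an RNA of the imprinted Dlk1 locus, was highest in replicate 3 on both array types, with 7512, 15136 and 47711 on an MOE430A probe set and 19292, 30345 and 83675 on an MOE430B probe set, and Dlk1 was not, with 16263, 30716 and 27118.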
